A study of Mus musculus with 12 samples.

How the data were processed

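RNA was measured by bulk sequencing of whole embryonic mouse lungs kept as explants. Per the labels' protocols, lungs of wild-type CD-1 embryos were isolated at embryonic day 12.5 and cultured in Matrigel at an air-liquid interface, RNA was purified with an RNeasy Micro kit, and libraries were made with the KAPA mRNA HyperPrep kit. The 12 libraries fall into 3 groups of 4: lungs at the start of treatment (Day 0), lungs cultured to Day 2 in the uncrosslinked polymer solution (Day 2 control) and lungs held for the same time by crosslinked polymer (Day 2 compression). Groups and replicate numbers were taken from the labels. The labels do not say whether libraries of a group came from separate animals, so every p-value measures the spread between these samples. The descriptions of compression replicates 2 and 3 share the number 13 with the letters A and B, whose meaning is not given in the sources used here.

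The authors deposited 1 table of raw read counts per gene symbol, with 1 column per library and 24421 symbols, of which 4505 have no count in any library. Per the submitters' processing notes, the authors used fastp and STAR and the mm10 genome build. Tool versions, the counting step, the gene annotation and the strand setting of the counts are not given in the sources used here. Because the strand setting is unknown, reads of genes whose exons overlap on opposite strands cannot be told apart. Because the treatment of reads that map to several places is unknown, values of near-identical family members (globins, keratins, Ifitm1, H2-Eb1, Lyz2) are uncertain to that extent. Coordinates were taken by symbol from an annotation of GRCm38, the assembly also called mm10. Of 117 genes whose values are given in the text, 112 matched by symbol, 4 by an older symbol and 1, the ribosomal precursor Rn45s, by neither. Exons of 13 shared more than 10% of their length with a gene on the opposite strand. On the same strand this held for 2 genes, Itgam (68.7% with Gm49368) and Mia (41.2% with Gm21983), whose counts may hold reads of the overlapping model or lack reads lost to it.

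Total counts ranged from 13979871 to 33249761 per library. A count of 0 in a library allows a level of up to 3 counts, which is 0.0902 to 0.215 CPM (counts scaled to the library total). Over the 4 libraries of a group the floor is 0.0322 CPM at Day 0, 0.0286 CPM in controls and 0.0260 CPM under compression. These floors, and the intervals of ratios given for genes with few counts, cover counting error only.

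Gene counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group (min.count 10, min.total.count 15), which left 15246 genes. Library sizes were scaled with TMM factors, all 12 libraries entered 1 quasi-likelihood fit with robust dispersion and the group as the only term, and each contrast was tested with glmQLFTest. P-values were adjusted over all genes tested by the Benjamini-Hochberg method and 0.05 was the threshold. Adjusted p-values of genes in the text come from this test unless another tool is named. CPM values use TMM-scaled library sizes and are given as mean ± SD. Principal components and list scores use log2 CPM with a prior count of 2. A list score is the mean log2 CPM over the members of the list minus its Day 0 mean.

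Before the data were examined, 50 gene lists covering signalling pathways, stress responses, proliferation, matrix and the cell types a lung explant could hold were fixed, as were the comparisons, the tests, the rule for genes named in the text and the first set of alternatives. Of the lists, 49 had at least 5 measured members and were tested. A list of mitochondrially encoded genes had too few. Some lists share members, so their results are not independent. Examples are Lyz2 (leukocytes, surfactant), Sftpc (distal tip, surfactant), Krt8 and Krt19 (general epithelium, mesothelium). Others are Kdr (endothelium, VEGF) and Aplnr and Tek (endothelium, angiopoietin and apelin). Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and adjusted over the 49 lists. Camera asks whether members of a list move further than other genes. The same lists were also tested with the correlation estimated from the residuals, with fry, which asks whether the members move 1 way on balance, and with an exact permutation test of the list score over the 70 ways to label 8 libraries, whose smallest two-sided p is 0.0286. Genes named are the 8 with the largest rise and the 8 with the largest fall among genes past the threshold with a mean of at least 1 CPM and groups that do not overlap (5 and 5 for compression against Day 0, predicted and clone genes left out), or, where fewer than 3 pass in a direction, the 5 with the smallest p. Every member of the list of VEGF ligands and receptors is named for compression against control, and up to 4 members per list with the smallest p (6 where camera called the list). Some genes that this rule selects are not reported here.

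The relation between the compression effect and the change over culture was measured as a Pearson correlation across genes, with the controls split so that no library entered both fold changes, averaged over the 6 ordered splits. Its exact p comes from relabelling the Day 2 libraries in the 70 possible ways. The values that shared control libraries give with no effect were simulated with unchanged groups and genes drawn independently.

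Alternatives in scaling and filtering were edgeR's relative log expression (RLE) or upper-quartile factors in place of TMM, and no filter. Other tools were DESeq2 1.42.0 and limma-voom with sample quality weights. Further alternatives were a fit of only the 8 libraries compared and the replicate number as a block. Each library was also left out in turn, and compression replicates 2 and 3 were summed to 1 library. Added after the data had been seen were the exact permutation test of list scores, the correlation without control replicate 4, DESeq2 without that library, edgeR without it and with compression replicates 2 and 3 summed, quality weights with these summed, and fits with sex as a covariate (Xist above or below 100 CPM), of only the 9 libraries with reads of 4 Y-linked genes, with 1 surrogate variable from sva 3.50.0, and without the ribosomal precursor Rn45s. The gene test was tested on simulated counts for compression against control with 15246 genes and 50 changed genes per fold size in each of 3 runs. edgeR recovered 2.67% of genes changed 1.2-fold, 62.7% at 1.5-fold, 86.7% at 2-fold and 92.7% at 3-fold, with a mean of 5.33 false calls. DESeq2 recovered 18.7%, 72.0%, 90.0% and 96.7% of the same genes with a mean of 26 false calls. A gene counted as recovered by edgeR only if called in its simulated direction, while for DESeq2 a call in either direction counted. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.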

Results

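Gene expression was profiled in mouse lungs isolated at embryonic day 12.5 and grown as explants. One day later, at Day 0, a 20% solution of PEG-HCC, a polymer that hardens where a two-photon laser crosslinks it, was placed around the lungs. In the compression group the polymer was crosslinked so that it restricted growth of the lung for 2 days, and in the control group the same solution was left uncrosslinked. The series title names VEGF, the main growth factor family of blood vessels, and congenital diaphragmatic hernia, a birth defect in which abdominal organs press on the developing lung. Each group (Day 0, Day 2 control and Day 2 compression) holds 4 libraries, and group values are given as mean ± SD (n = 4). Total counts were 13979871 to 33249761 at Day 0, 15452117 to 30805341 in controls and 25680019 to 31739019 under compression. The lowest total among the Day 2 libraries was that of control replicate 4.

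Sampling day separated the libraries most. The first principal component held 60.5% of the variance and placed the Day 0 libraries between -68.0 and -52.8, the controls between 8.72 and 27.9 and the compression libraries between 34.4 and 43.1. The compression group lay 18.3 units beyond the control group on this component (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 can give). The second component held 9.63% and did not follow the groups. Control replicates 1 to 3 (25.5, 28.3 and 8.18) and compression replicate 1 (22.6) had positive scores on it, while control replicate 4 (-16.9) and compression replicates 2 to 4 (-17.6, -15.3 and -21.9) had negative scores.

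**Figure D1:**
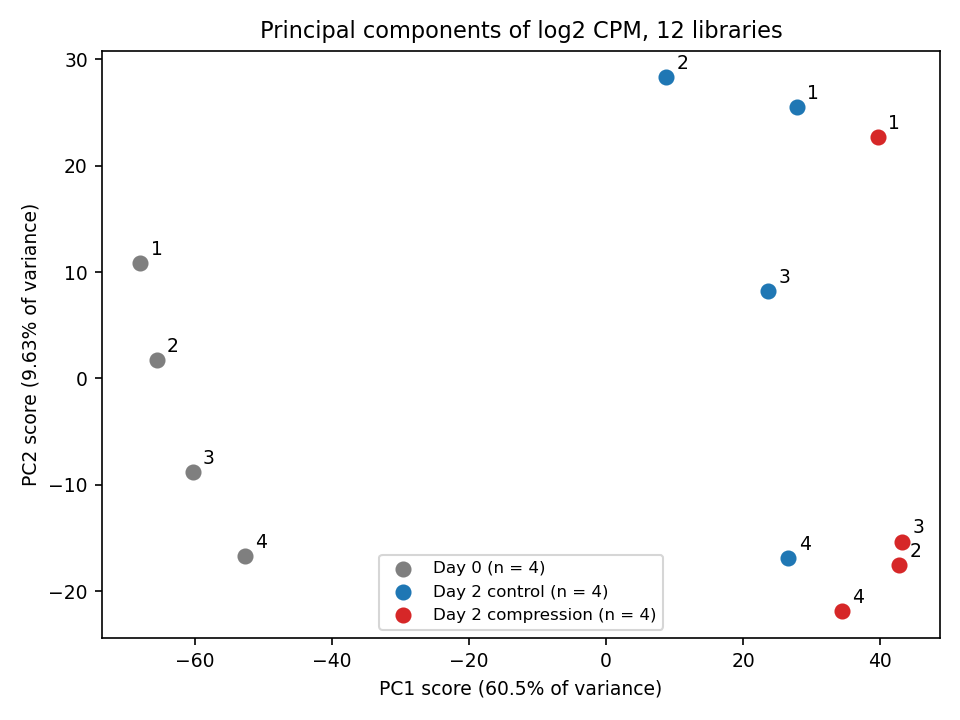
Scores of the 12 libraries on the first principal component (horizontal axis, 60.5% of variance) and the second (vertical axis, 9.63%), both in units of log2 CPM. Points are libraries, coloured by group and numbered by replicate, and the Day 2 compression libraries lie between 34.4 and 43.1 on the horizontal axis, to the right of all controls.

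Single libraries differed in ways that the groups do not describe. Control replicate 4 held transcripts of liver: albumin (Alb) stood at 646 CPM and alpha-fetoprotein (Afp) at 755 CPM, 290-fold and 46.6-fold above the highest other library. Xist, which is transcribed from the inactive X chromosome of females, was above 100 CPM in control replicates 2 and 3 and compression replicate 1, and the other 9 libraries had reads of Y-linked genes. Compression replicates 2 and 3 were closer to each other than the members of the other within-group pairs. Their dispersion was 8.757e-04, against 0.00557 to 0.0427 in the other pairs. Their mean chi-square per gene was 4.09, against at least 7.52 in the other pairs, which leaves open whether they came from separate lungs. They were counted as 2 samples, as labelled. The exact permutation tests and the splits into 4 and 4 also count them as 2 and were not rerun with them summed. If they came from 1 lung, these tests overstate the number of independent samples. The ribosomal precursor Rn45s took 0.553% to 5.64% of counts, and its mean share was 1.51 percentage points higher under compression than in controls (exact permutation p = 0.229).

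The comparison of compression with control at Day 2 asks what crosslinked polymer that restricts growth does to the lung. The groups differ in the crosslinking of the polymer as well as in restriction. Effects of restriction and of crosslinking cannot be told apart here. No gene passed the threshold with edgeR. The lowest adjusted p was 0.0767, reached by 4 genes, each with all 4 compression libraries above all 4 controls. Penk, which encodes the opioid precursor proenkephalin, averaged 35.1 ± 3.25 CPM under compression and 21.0 ± 1.38 in controls (log2 fold change 0.74, SE 0.11). The interferon-inducible membrane protein gene Ifitm1 stood at 14.1 ± 2.39 against 7.75 ± 0.308 CPM (0.86, SE 0.13). The calcification inhibitor gene Mgp stood at 68.5 ± 4.99 against 47.3 ± 2.86 CPM (0.53, SE 0.08), and the MHC class II gene H2-Eb1 at 2.80 ± 0.246 against 0.552 ± 0.130 CPM (2.36, SE 0.37). Itln1, which encodes a lectin, was next (2.86, SE 0.52, adjusted p = 0.224). Among genes with lower values, the smallest p-values were those of Tspyl2 (-0.34), Heatr1 (-0.31), a factor of ribosome assembly, Podxl (-0.31), a sialomucin of podocytes, vessels and mesothelium, the host RNA Snhg17 (-0.32) and the synaptotagmin gene Syt2 (-1.03), with adjusted p-values between 0.224 and 0.252. In the GRCm38 (mm10) assembly Penk lies on chromosome 4 (4133536 to 4138815, minus strand), Ifitm1 on chromosome 7 (140967429 to 140969827, plus strand), Mgp on chromosome 6 (136872435 to 136875823, minus strand) and H2-Eb1 on chromosome 17 (34305867 to 34316674, plus strand).

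**Figure D2:**
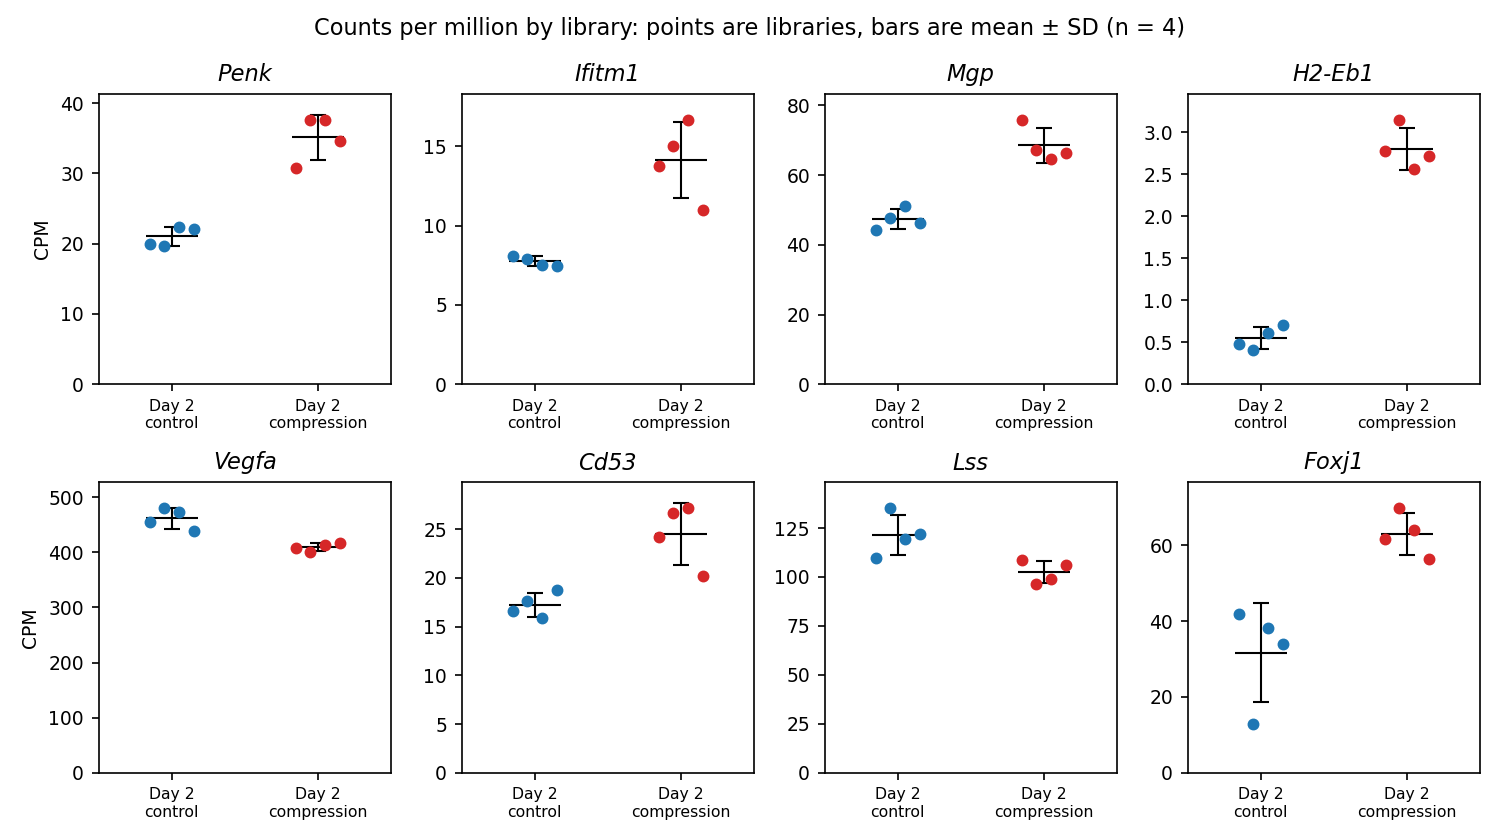
CPM (vertical axis, from 0) of 8 genes in the 4 Day 2 control and 4 Day 2 compression libraries; points are libraries and bars are mean ± SD. Penk, Ifitm1, Mgp and H2-Eb1 have the lowest adjusted p (0.0767), and Vegfa lies lower in all compression libraries without passing the test.

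At an unadjusted p under 0.05, 1839 genes differed, 1026 higher and 813 lower under compression, where 762 would be expected on average by chance. Genes are correlated, so chance can give more. Of the 35 splits of these libraries into 4 and 4, 4 gave as many, the real one among them. The groups did not overlap for 5.77% of genes, against 2.86% by chance. DESeq2 called 72 genes (52 higher, 20 lower), among them Penk (adjusted p = 1.677e-06), and limma-voom with quality weights called 1913 (1125 higher, 788 lower), which became 191 when compression replicates 2 and 3 were summed. edgeR called 53 genes without control replicate 4 (52 higher, 1 lower), 19 without compression replicate 1, and 1 each without control replicate 3 (Itln1) and without compression replicate 4 (Ifitm1). Without control replicate 4 the adjusted p-values of Penk, Ifitm1, Mgp and H2-Eb1 were 0.0187, 0.0275, 0.0306 and 0.0262. Other settings weakened the result. With compression replicates 2 and 3 summed, edgeR gave 1183 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.320. The lowest adjusted p was 0.205 without control replicate 1 and 0.301 without control replicate 2. It was 0.418 without compression replicate 2 and 0.265 without compression replicate 3.

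The VEGF ligands and receptors were followed as a group because the series names the pathway. In the fit of all 12 libraries, none of the 10 measured genes differed at an unadjusted p under 0.05. None passed when adjusted over the list alone. Neither camera (adjusted p = 0.402), fry (0.619) nor the exact permutation of the score (0.579) called the list. Vegfa, the main ligand (chromosome 17, 46016993 to 46032377, minus strand), stood at 410 ± 7.64 CPM under compression and 462 ± 18.8 CPM in controls, with no overlap between the groups. Its fold change of -0.17 (SE 0.15, adjusted p = 0.633) has a 95% interval from -0.49 to 0.15 on the log2 scale. This SE comes from the fit of all 12 libraries, Day 0 included, and is not the spread within the 2 groups compared. A fit of only the 8 libraries compared did not call Vegfa either, at the threshold adjusted over all genes. The unadjusted p of Vegfa in that fit is not given here. The other ligands Vegfb (0.15), Vegfc (0.17), Figf, which encodes VEGF-D (0.12), and Pgf (0.10) had small positive fold changes. The receptors Kdr (0.11), Flt1 (0.45, SE 0.46), Flt4 (-0.12), Nrp1 (0.16) and Nrp2 (0.02) stood between adjusted p-values of 0.642 and 0.948. The sign of Nrp2 turned with quality weights (-0.03, and -0.02 with compression replicates 2 and 3 summed), in the 9 libraries with Y-linked reads (-0.02), without compression replicate 1 (-0.06) and, to just under 0, without control replicate 3, and that of Flt4 without control replicate 2 (0.01).

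Camera with the preset correlation called 17 of 49 lists, 13 higher and 4 lower under compression. With an estimated correlation it called none, with adjusted p-values of 0.795 to 0.825 for these lists, and neither fry (lowest adjusted p = 0.414) nor the exact permutation of list scores (lowest adjusted p = 0.525) called any. All 23 genes of macrophages and other leukocytes had positive fold changes, 14 at an unadjusted p under 0.05 and 13 when adjusted over the list alone (camera adjusted p = 1.09e-12, adjusted p = 0.795 with an estimated correlation). Examples are the tetraspanin gene Cd53 (0.51), the chemokine gene Pf4 (6.63 against 3.33 CPM), the integrin gene Itgam (1.33) and Adgre1, which encodes the macrophage marker F4/80 (0.70). The list score was at least 0.722 in each compression library. Control replicate 4, the library with liver transcripts, scored 0.906 and the other controls 0.0806 to 0.329 (exact permutation p = 0.0857). Itgam passed edgeR's threshold without control replicate 4 (adjusted p = 0.00605). In that fit Il33, a cytokine gene of the inflammatory list, also passed (1.14, adjusted p = 0.0220).

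Epithelial lists lay higher under compression. Of 19 genes of surfactant and alveolar differentiation, 16 had positive fold changes and 9 passed when adjusted over the list alone (camera adjusted p = 3.35e-05, adjusted p = 0.795 with an estimated correlation). The surfactant protein gene Sftpc averaged 1017 ± 255 CPM against 574 ± 136, the protease gene Napsa 3.04 ± 1.124 against 1.29 ± 0.403, and the phosphate carrier gene Slc34a2 46.7 ± 23.6 against 7.59 ± 6.29. Of 16 proximal airway genes, 12 were positive and none passed when adjusted over the list alone (camera adjusted p = 0.00446, adjusted p = 0.795 with an estimated correlation, and 0.151 without control replicate 4). Foxj1, the regulator of motile cilia, stood at 63.0 ± 5.50 against 31.7 ± 13.01 CPM and the club cell gene Cyp2f2 at 53.9 ± 18.6 against 25.97 ± 7.38 CPM. The general epithelium list (17 of 24 positive, camera adjusted p = 0.00992, adjusted p = 0.825 with an estimated correlation) lost its call without control replicate 4 (0.166) or compression replicate 4 (0.151). The distal tip list, with Id2 (0.44) and Mia (0.33), had 9 of 15 positive and 3 past the threshold when adjusted over the list alone. Its camera adjusted p was 0.00813 (adjusted p = 0.795 with an estimated correlation), and 0.110 without control replicate 1 and 0.164 without compression replicate 4.

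Lists that lay lower were cholesterol synthesis, DNA replication and the stress responses of protein folding and amino acid supply. Of 21 cholesterol synthesis genes 19 had negative fold changes, 6 at an unadjusted p under 0.05 and 2 when adjusted over the list alone (camera adjusted p = 9.42e-07, adjusted p = 0.795 with an estimated correlation; exact permutation p of the score = 0.0286). The enzyme genes Lss and Cyp51 had log2 fold changes of -0.24 and -0.36. In the S phase list 24 of 26 genes were negative (camera adjusted p = 0.00011, adjusted p = 0.825 with an estimated correlation), with Cdc6 at -0.27 and the helicase subunit Mcm6 at -0.15. The unfolded protein response (17 of 18 negative, camera adjusted p = 1.52e-04, adjusted p = 0.825 with an estimated correlation), with the chaperones Hspa5 (-0.34) and Hsp90b1 (-0.31), rested on control replicate 4. That library scored 1.001 and the other controls 0.195 to 0.617, and without it the adjusted p was 0.371. The integrated stress response list (18 of 22 negative, camera adjusted p = 0.00412, adjusted p = 0.825 with an estimated correlation), with the asparagine synthetase gene Asns (-0.49), stood at 0.858 without control replicate 4 and 0.185 without compression replicate 1. None of these S phase and stress genes passed when adjusted over the list alone.

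Among the remaining lists called as higher, 14 of 16 matrix proteases and inhibitors were positive, with the macrophage elastase gene Mmp12 at 1.55 (camera adjusted p = 0.00122, adjusted p = 0.795 with an estimated correlation). Of 50 ribosomal protein genes 47 were positive by small amounts (median 0.10, camera adjusted p = 0.00011, adjusted p = 0.825 with an estimated correlation). The interferon response, with Irf7 (1.82) and Mx1 (1.94), came mainly from compression replicate 1, which scored 2.19 while the other compression libraries scored -0.0298 to 0.477. Its camera adjusted p was 1.29e-04 (adjusted p = 0.825 with an estimated correlation) and 0.505 without that library. The inflammatory list, with Il33 (0.93) and the NF-kB inhibitor gene Nfkbia (0.30), had 17 of 21 positive and 2 past the threshold when adjusted over the list alone. Its adjusted p was 0.00483 (adjusted p = 0.795 with an estimated correlation) and 0.156 without compression replicate 1, the highest of the compression libraries at 2.03. Control replicate 4 was the highest control at 1.75. The cartilage list, with Col9a1 (0.40) and Hapln1 (0.57), had 11 of 14 positive (0.00446, adjusted p = 0.795 with an estimated correlation, 0.0864 without compression replicate 1). Immediate early genes (Junb 0.55), elastic fibre genes (Mfap4 0.32) and BMP signalling genes (Id1 0.46) were called at 0.0194, 0.0382 and 0.0437 (adjusted p = 0.825, 0.825 and 0.795 with an estimated correlation). Omission of control replicate 1 took them to 0.202, 0.186 and 0.164, omission of compression replicate 4 to 0.0849, 0.315 and 0.333, and omission of compression replicate 2 to 0.0763, 0.0614 and 0.0667. Without control replicate 4 the elastic fibre list stood at 0.0567 and BMP signalling at 0.121. The mesothelium list was not called (6 of 14 positive, adjusted p = 0.0862), with the uroplakin gene Upk3b at -0.68 and the retinaldehyde dehydrogenase gene Aldh1a2 at -0.58. It was called as lower without control replicate 4 (0.00673), without control replicate 3 (0.00672) and with the replicate number as a block (0.0423), but had an adjusted p = 0.825 with an estimated correlation. The endothelium list had 21 of 25 positive and was not called (0.116), but was called as higher without control replicate 4 (0.0142), control replicate 3 (0.0110) or compression replicate 1 (0.0113) and with the block (0.0195). It had an adjusted p = 0.849 with an estimated correlation.

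The comparison of controls with Day 0 gives the change over 2 days of culture with unrestricted growth. The controls also spent these 2 days in the uncrosslinked polymer solution, for which the labels give no days at Day 0. Effects of time and of the solution cannot be told apart here. In all, 6131 genes changed, 3441 up and 2690 down, and 1415 of them changed at least 2-fold (1034 up, 381 down). Foxn4, a transcription factor gene of multiciliated cells (chromosome 5, 114254164 to 114274418, minus strand), had 0 counts in all Day 0 libraries and 5.38 ± 2.49 CPM in controls, at least 167-fold higher than the Day 0 floor, and Meig1 was at least 68.7-fold higher. Sec14l3 had 1 count at Day 0 and 1916 in controls, a ratio of 1703 (95% counting interval 305 to 67302). The ratios were 570 (102 to 22539) for the dynein light chain gene Dynlrb2, 361 (123 to 1755) for Cdc20b, which lies in a multiciliated cell locus, 346 (95.4 to 2860) for Ccdc108, 262 (46.7 to 10392) for the tektin gene Tekt4 and 119 (40.6 to 581) for the axonemal gene Wdr63. The adjusted p-values of these 8 genes lay between 7.83e-06 and 2.99e-04.

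Of 25 endothelial genes 23 fell and none rose (camera adjusted p = 7.49e-25, adjusted p = 0.242 with an estimated correlation). The apelin receptor gene Aplnr went from 54.2 ± 14.01 CPM at Day 0 to 2.64 ± 1.77 CPM in controls (-4.40, SE 0.41, adjusted p = 9.30e-06), the transcription factor gene Sox17 from 11.96 ± 2.33 to 0.943 ± 0.564 CPM (-3.70) and VE-cadherin (Cdh5) from 94.0 ± 19.0 to 15.8 ± 5.75 CPM (-2.60). Egfl7 (-2.17) and the angiopoietin receptor gene Tek (-3.08) fell too, and the angiopoietin and apelin list had 6 of 10 genes down and 2 up (adjusted p = 2.44e-04, and adjusted p = 0.262 with an estimated correlation). Among the VEGF genes 4 fell and 2 rose. The receptors Flt1 (-3.22) and Kdr (-1.69) and the ligand Pgf (-1.04) fell and the co-receptor Nrp2 rose (0.52), and camera did not call the VEGF list (adjusted p = 0.258, and adjusted p = 0.554 with an estimated correlation). Fry called it as lower (0.0102), and the exact permutation did not call it (0.0538). Of 9 measured erythroid genes 4 fell and none rose, and the list was called (adjusted p = 4.45e-04, adjusted p = 0.303 with an estimated correlation). The embryonic globins Hba-x (-3.53), Hbb-bh1 (-3.34) and Hbb-y (-3.29), which primitive red cells make, and the haem synthesis gene Alas2 (-3.38) were the 4. Control replicate 4, with its liver transcripts, had an erythroid score of -0.767 against -2.71 to -2.39 in the other controls. The steroid dehydrogenase gene Hsd3b6 (-3.49) and the secreted protein gene Bpifb1 (-3.41) completed the 8 largest falls.

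**Figure D3:**
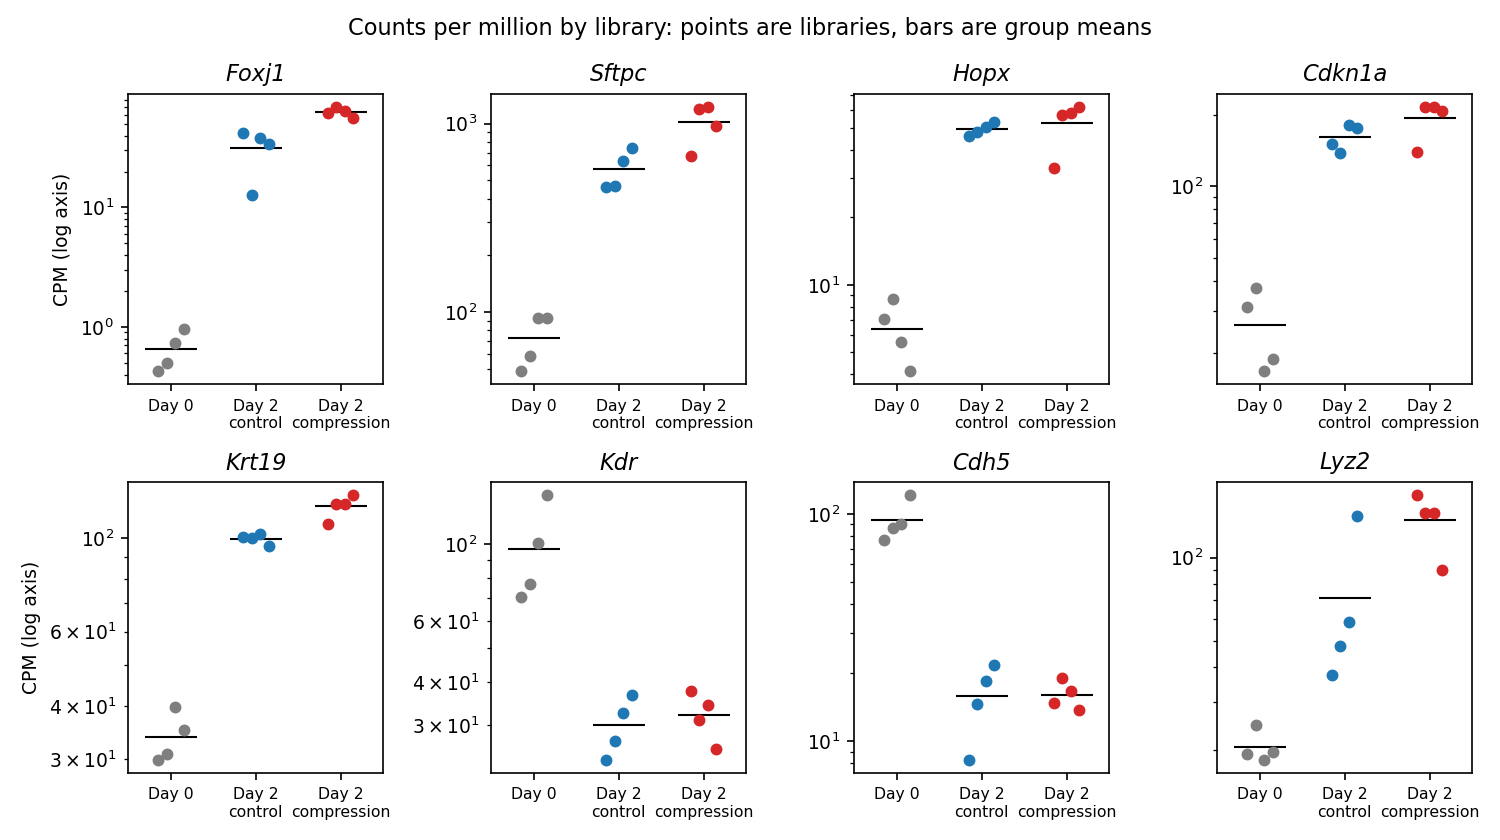
CPM on a log axis (vertical) of 8 genes in the 3 groups; points are libraries and bars are group means (n = 4). Foxj1, Sftpc, Hopx, Cdkn1a, Krt19 and Lyz2 lie higher in all Day 2 libraries than in all Day 0 libraries, and Kdr and Cdh5 lie lower.

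Of 24 general epithelial genes 22 rose and none fell (adjusted p = 5.08e-18, adjusted p = 0.181 with an estimated correlation), with Krt19 (1.55), Krt8 (0.94) and E-cadherin, Cdh1 (1.02), each with an adjusted p of at most 2.26e-06. Surfactant and alveolar genes had 12 of 19 up and 1 down (adjusted p = 1.47e-09, adjusted p = 0.262 with an estimated correlation). Sftpc rose from 72.9 ± 23.0 to 574 ± 136 CPM, Hopx from 6.33 ± 1.92 to 49.2 ± 3.16 CPM and Ager, a gene of flat alveolar cells, from 19.8 ± 0.692 to 104 ± 18.5 CPM. Proximal airway genes had 10 of 16 up (adjusted p = 2.93e-05, adjusted p = 0.298 with an estimated correlation). Foxj1 rose from 0.655 ± 0.241 to 31.7 ± 13.01 CPM and Cyp2f2 from 0.319 ± 0.423 to 25.97 ± 7.38 CPM. Targets of p53 rose, 18 of 20, and 2 fell (adjusted p = 1.78e-11, adjusted p = 0.161 with an estimated correlation), with the cell cycle inhibitor gene Cdkn1a at 2.65, Ccng1 at 1.43 and the pro-apoptotic gene Pmaip1 at 2.31. In the mesothelium list 7 of 14 rose and 1 fell (adjusted p = 7.50e-05, adjusted p = 0.298 with an estimated correlation), with mesothelin, Msln, at 4.09 and Gpm6a at 1.72. Lung mesenchyme genes had 12 of 19 down and 2 up (adjusted p = 7.50e-05, adjusted p = 0.292 with an estimated correlation), with Hoxa5 (-0.86), the Wnt effector Lef1 (-1.01) and the integrin gene Itga8 (-0.76).

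Signalling and matrix lists moved too. FGF ligands and receptors had 8 of 11 up and 1 down, Fgf7 (2.34) and Fgf10 (0.56) among the rises and Fgfr1 (-0.44) the fall (adjusted p = 0.00710, adjusted p = 0.262 with an estimated correlation). Hedgehog genes had 8 of 13 down, Gli3 (-0.71) and Gas1 (-0.76) among them, while the epithelial ligand gene Shh (0.66) and the antagonist gene Hhip (0.78) rose (adjusted p = 0.0369, adjusted p = 0.533 with an estimated correlation). The camera call of this list was lost without control replicate 4 (0.121) and with the replicate number as a block (0.0776). YAP/TAZ targets had 13 of 21 up and 2 down, with Ctgf at 2.17 (adjusted p = 0.00710, adjusted p = 0.336 with an estimated correlation). Fibrillar collagens and crosslinking genes had 12 of 24 up and 3 down, with Lox at 1.09 and Tnc at 1.81 (adjusted p = 0.00803, adjusted p = 0.563 with an estimated correlation). Cholesterol synthesis had 16 of 21 up, with the regulator gene Insig1 at 0.89 (adjusted p = 3.33e-05, adjusted p = 0.533 with an estimated correlation). The unfolded protein response had 14 of 18 up, with the chaperone gene Calr at 0.58 (adjusted p = 2.44e-04, adjusted p = 0.646 with an estimated correlation). Stra6, the cell-surface carrier for retinol, fell by 2.14 on the log2 scale. Leukocyte genes had 8 of 23 up, with Cd68 (1.09) and Lyz2 (1.79), which is also a member of the surfactant and alveolar list. Their call (adjusted p = 0.0468, adjusted p = 0.859 with an estimated correlation) was lost without control replicate 4 (0.165), Day 0 replicate 1 (0.0789) or Day 0 replicate 2 (0.0557).

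In this comparison 22 lists were called, 15 up and 7 down, none with an estimated correlation (lowest adjusted p = 0.161), and fry called 24. The exact permutation test called none after adjustment (lowest adjusted p = 0.0538), with 26 lists at the smallest p it can give.

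The comparison of compression with Day 0 gives the change over 2 days under restricted growth. Time and exposure to the polymer cannot be told apart here either. In all, 7489 genes changed, 4062 up and 3427 down, and 1783 changed at least 2-fold (1384 up, 399 down). The count depends on the near-identical compression replicates 2 and 3, and was 6658 with these summed. Without compression replicate 1, 2, 3 or 4 it was 7597, 6555, 6661 or 7224. Foxn4 was at least 322-fold higher than the Day 0 floor, Meig1 at least 155-fold and Drc7, a gene of the ciliary dynein regulatory complex, at least 79.3-fold. Sec14l3 and Dynlrb2 had ratios of 3901 (700 to 154098) and 1162 (208 to 45930). Large falls were those of the red cell anion exchanger gene Slc4a1 (-4.81), Aplnr (-4.36), Alas2 (-3.91) and Hbb-bh1 (-3.65). Adjusted p-values of these 9 genes lay between 1.71e-06 and 0.00764.

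Of 25 endothelial genes 23 fell (adjusted p = 7.39e-18, adjusted p = 0.299 with an estimated correlation), with Cdh5 at -2.55. In the angiopoietin and apelin list 6 of 10 fell and 2 rose, with Tek at -2.89 (adjusted p = 0.00263, adjusted p = 0.400 with an estimated correlation). Among VEGF genes 4 fell and 2 rose, Flt1 (-2.78), Kdr (-1.59) and Pgf (-0.93) among the falls and Nrp2 (0.53) among the rises. The list was not called by camera (adjusted p = 0.466, and adjusted p = 0.869 with an estimated correlation) or fry (0.0729), and was called as lower by the exact permutation (0.0452). Of 9 erythroid genes 5 fell (adjusted p = 9.91e-04, adjusted p = 0.400 with an estimated correlation). General epithelium had 22 of 24 genes up (adjusted p = 7.39e-18, adjusted p = 0.1997 with an estimated correlation), with Krt19 at 1.81 and Krt8 at 1.03. Surfactant and alveolar genes had 16 of 19 up and 1 down (adjusted p = 1.83e-11, adjusted p = 0.299 with an estimated correlation), with Sftpc at 3.80 and Hopx at 3.09, and proximal airway genes 12 of 16 up (adjusted p = 5.66e-06, adjusted p = 0.299 with an estimated correlation), with Foxj1 at 63.0 ± 5.50 CPM and Cyp2f2 at 7.06. Targets of p53 had 17 of 20 up and 1 down, with Cdkn1a at 2.91 (adjusted p = 2.04e-10, adjusted p = 0.1997 with an estimated correlation).

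Leukocyte genes had 15 of 23 up and none down (adjusted p = 3.52e-05, adjusted p = 0.531 with an estimated correlation). Lyz2 rose from 20.6 ± 2.79 to 137 ± 33.2 CPM, Itgam from 3.07 ± 0.564 to 16.8 ± 2.75 CPM, Cd53 by 1.54 and Cd68 by 1.47 on the log2 scale. In the S phase list 13 of 26 genes fell and none rose, with Mcm4 (-0.42) and Mcm5 (-0.33) (adjusted p = 0.00678, adjusted p = 0.869 with an estimated correlation). Mesothelin, Msln (4.52), Lox (1.25) and the YAP/TAZ targets Cyr61 (2.15) and Ctgf (2.61) rose. In this comparison 17 lists were called, 11 up and 6 down, none with an estimated correlation (lowest adjusted p = 0.1997). Fry called 25, and the exact permutation of list scores called 31 (22 up, 9 down), all at the smallest p it can give.

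**Figure D4:**
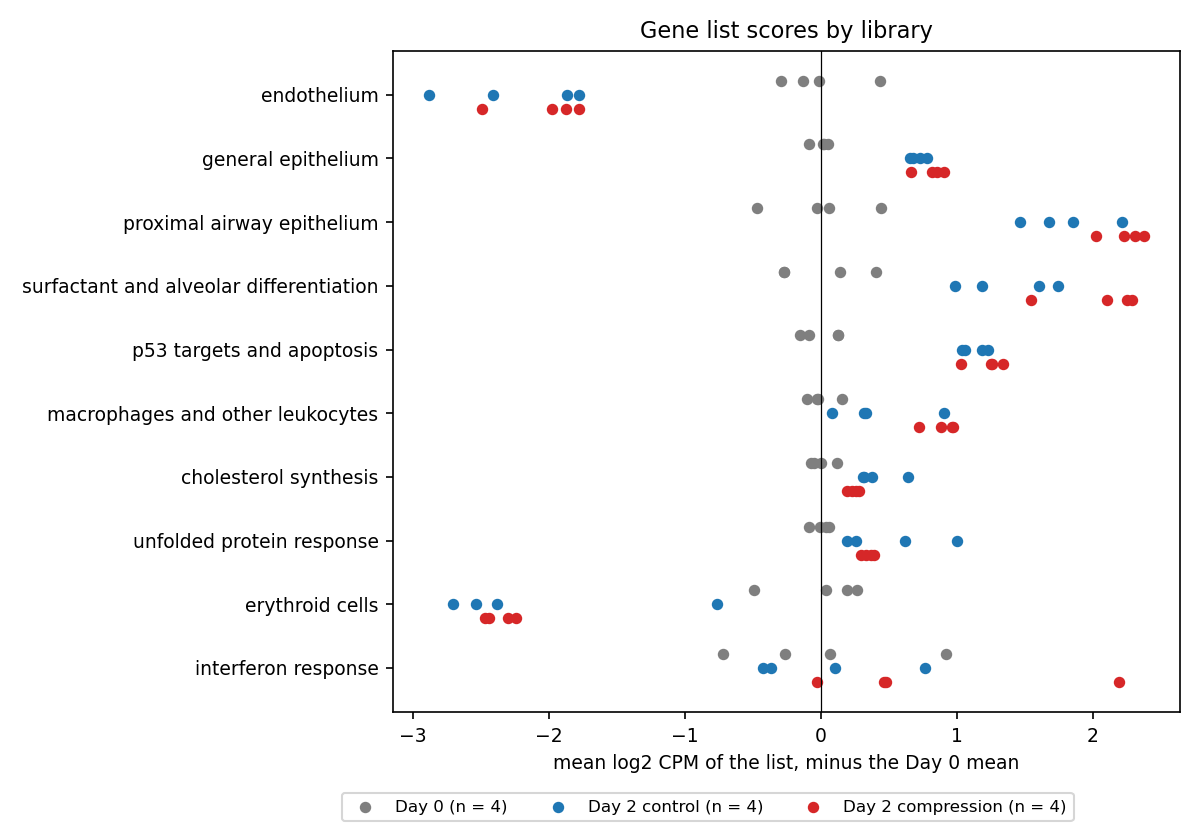
Scores of 10 gene lists (horizontal axis, mean log2 CPM of the list minus its Day 0 mean) in each of the 12 libraries; points are libraries, coloured by group. Endothelium lies at -1.78 or below in all Day 2 libraries, and control replicate 4 is the highest control for leukocytes (0.906) and erythroid cells (-0.767).

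Genes that changed with and without compression were mostly shared. Both Day 2 groups differed from Day 0 in the same direction for 5398 genes, 3062 up and 2336 down, which is 88.0% of the genes changed in controls. Independent lists of these lengths would share 1521. Because both comparisons use the same Day 0 libraries, these libraries were also split between the comparisons, which gave a mean of 3684 shared genes (3436 to 4061). No gene was up in controls and down under compression, and 1 was down in controls and up under compression.

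Whether compression moved genes along the change over culture was measured across genes. Across 15246 genes, the fold change of compression over control correlated with that of control over Day 0 at r = 0.305 when the controls were split (0.202 to 0.395 over the 6 splits). Genes are not independent replicates. Of the 70 labellings of the Day 2 libraries 2 gave a correlation as high, and the two-sided exact permutation p was 0.114. Without control replicate 4, r was 0.201 (0.0273 to 0.321). Splits without that library hold fewer controls, and no other control was left out for comparison. With all controls in both fold changes r was 0.232 and the covariance 0.0478. Unchanged simulated groups gave an r of -0.490 and a covariance of -0.0242 (-0.0261 to -0.0225 in 20 simulations). The simulations drew genes independently and held no change over culture. Their r is therefore not comparable with 0.232, and their range is too narrow to serve as a test. They show only the direction in which shared controls move these values.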

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

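The tests of liver markers, of the libraries that cross the groups, of sex and of the correlation without control replicate 4 were chosen after the results were seen. A library is listed here when its value stood far from the other 3 of its group, which chance gives in about 1 of 20 groups. Of 405 groups examined (genes only where the group mean was at least 1 CPM), 27 held such a value, 6.67%. Compression replicates 2 and 3 lie so close together that another compression library stands apart more easily.

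Control replicate 4 had the lowest total count of its group, 15452117 (15.5 megacounts, others 29108637 to 30805341), and liver transcripts. Alb stood at 646 CPM (others at most 0.407) and Afp at 755 CPM (others at most 0.610), and the erythroid score at -0.767 against -2.71 to -2.39. Of 27 liver markers with at least 10 counts there, 25 lay above all other libraries, with a median fold of 59.6 over the highest of them, and 3 of the 29 markers tested reached 1 CPM at the median of the other 11 libraries. This indicates that liver RNA or tissue may have entered the library. The general epithelium list, which does not tell lung from other epithelial organs, lay a median of -0.0509 log2 from the other controls. The distal tip epithelium list lay at 0.109 and the lung mesenchyme list at -4.0e-04, which argues against another organ in place of the lung. No biological explanation was tested.

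Compression replicate 1 stood apart on the second principal component, at 22.6 against -21.9 to -15.3. Its Xist level was 2837 CPM against at most 0.490 in the other compression libraries. Its inflammatory score was 2.03 (others 1.12 to 1.24), its NRF2 target score 0.270 (0.431 to 0.439) and its mesothelium score 0.971 (others at least 0.711). Its log2 CPM was 5.13 for Asns, 5.49 for Cd68, 7.12 for Cdkn1a, 4.25 for Ctgf, -0.13 for Flt1, 5.06 for Hopx and 8.42 for Mfap4, each below the other compression libraries. Control replicate 4 had an inflammatory score of 1.75 against 0.770 to 0.931.

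The other values are these. Control replicate 2 scored 0.732 for FGF ligands and receptors (0.775 to 0.781), had Foxn4 at a log2 CPM of 0.84 (2.59 to 2.82) and Aldoc at 4.69 (4.37 to 4.41). Control replicate 1 had Egfl7 at 3.42 (3.87 to 3.93) and Lox at 9.10 (8.85 to 8.86). Day 0 replicate 1 had Lox at 8.04 (7.72 to 7.76). Day 0 replicate 4 had Flt1 at 4.37 (3.35 to 3.48) and Hbb-bh1 at 4.17 (5.84 to 5.96). Compression replicate 4 had Mcm5 at 7.30 (7.20 to 7.21) and Sec14l3 at 4.76 (others at least 5.52).

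The 8 Day 2 libraries also divided across the groups. Control replicate 4 with compression replicates 2 to 4 differed from the rest in 474 genes (228 higher, 246 lower), 8 of 23 leukocyte genes among the higher ones; Lpl (1.02), Laptm5 (0.66) and Itgax (2.69) were chosen as examples after their values were seen. Exchanged labels of control replicate 4 and compression replicate 1 stay open: over 444 genes that separate the other Day 2 libraries by group, with 0 at the other controls and 1 at the other compression libraries, the former had a median position of 0.633 (quartiles 0.395 to 0.922) and the latter 0.238 (-0.00186 to 0.587), so both lie between the groups. The first principal component goes against an exchange without excluding it, with control replicate 4 at 26.6 among the controls (8.72 to 27.9) and compression replicate 1 at 39.7 among the compression libraries (34.4 to 43.1), while the second divides them the other way. The sex of the embryo stays open too: all 3 libraries with Xist lie in the set opposite control replicate 4, and the only other library of that set, control replicate 1 with Y-linked reads, had a median position of -0.0637 over 74 genes (0 is the mean of its own set, 1 that of the other), which goes against sex, but 1 library does not exclude it.

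The compression effect correlated across genes with the change from Day 0 to Day 2 at a split r of 0.305, but the two-sided exact permutation p was 0.114 and another labelling gave 0.328, so chance is not excluded. Without control replicate 4, the library with liver transcripts, r was 0.201, with splits from 0.0273 to 0.321. Each split then holds fewer controls, which adds noise whatever the library left out. No other control was left out for comparison. Whether liver RNA contributes cannot be decided from this and stays open. In the libraries with Y-linked reads r was 0.237 (0.234 to 0.239 over 2 splits). The only controls among them are replicates 1 and 4, so the library with liver transcripts enters both splits. Sex as the whole cause therefore stays open. A biological effect of compression is named by the design and stays open.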

How the results depend on the processing

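The fits without control replicate 4 combined with another change, with summed replicates and quality weights, with sex, with Y-linked reads, with a surrogate variable and without Rn45s, and the exact test of list scores, were chosen after the data were seen. All genes named for the Day 0 comparisons kept their direction and side of the threshold in every alternative run. For compression against control, where edgeR called 0 genes, DESeq2 called 72, DESeq2 without control replicate 4 276, limma-voom with quality weights 1913, the same with compression replicates 2 and 3 summed 191, a fit of only the 8 libraries 4, and edgeR without control replicate 4 and with the replicates summed 10. Leaving out each library gave 0 to 53. The quality weights gave compression replicates 2 and 3 the highest weights, 4.49 and 2.33; otherwise the cause was not tested. Other scalings, no filter, the summed replicates alone, sex, the Y-linked subset, a surrogate variable and omission of Rn45s called 0.

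Lists called fell from 17 to 0 with an estimated correlation, 0 with fry and 0 with the exact permutation for compression against control. For control against Day 0 they fell from 22 to 0 with an estimated correlation and 0 with the exact permutation, while fry called 24. For compression against Day 0 they went from 17 to 0 with an estimated correlation, 25 with fry and 31 with the exact permutation. The 0 and the 31 follow from the smallest p of the exact test, 0.0286, which 26 and 31 lists reached and which adjusts to 0.0538 and 0.0452. These tests ask different questions, and otherwise the cause was not tested. The split correlation of 0.305 moved to 0.396 over only the genes changed between Day 0 and controls and to 0.201 without control replicate 4; the cause was not tested.

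The replicate numbers were not taken to pair the samples. Deviations of same-numbered libraries correlated from -0.181 to 0.166 for compression and control, -0.141 to 0.108 for compression and Day 0 and 0.0487 to 0.112 for control and Day 0, where 1, 1 and 2 of 4 correlated best with their own number. With the number as a block, edgeR called 0 genes for compression against control (lowest adjusted p = 0.0634) and 20 lists, 6569 genes for control against Day 0 and 7895 for compression against Day 0.

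Splits of the same 8 libraries into 4 and 4 show where a chance division of the libraries is unlikely. It is unlikely for the genes changed from Day 0. There 1 of 35 splits, the real one, gave 6131 in controls (highest other 4) and 1 of 35 gave 7489 under compression (highest other 1). A share of 1 in 35 is the smallest that these splits can give, and they treat the libraries as independent samples. For compression against control a real count of 0 is reached by 35 of 35 splits whatever the data (highest other 474), so that count says nothing. Chance is not excluded there, as 4 of 35 gave as many genes at an unadjusted p under 0.05 (1839, highest other 3654). The split with 474 calls sets control replicate 4 with compression replicates 2 to 4, which points to a structure of the samples. Nor does the number of lists that camera called exclude it, as 19 of 35 splits gave as many for compression against control (17, highest other 29), 11 for control against Day 0 (22, highest other 26) and 18 for compression against Day 0 (17, highest other 26). For compression against Day 0 the exact permutation of scores called all 17 lists (adjusted p = 0.0452), each at the smallest p it can give. For control against Day 0 the exact permutation called none of the 22, with the leukocyte, basement membrane and pericyte lists at up to 0.189 and the others at 0.0538, while fry called 19. The number of lists tied at the smallest p, 31 against 26, decides on which side of the threshold it falls. These calls therefore do not exclude chance for a single list. At 4 libraries a group, edgeR recovered 2.67% and DESeq2 18.7% of genes simulated with a 1.2-fold change.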

Other observations

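The exact test of list scores was chosen after the data were seen. Camera called none of the lists of retinoic acid signalling, glycolysis, hypoxia response, mitochondrial respiratory chain and skeletal muscle in either Day 0 comparison with all libraries. For compression against Day 0, fry called retinoic acid signalling (5.8e-04), glycolysis (0.0347) and skeletal muscle (0.0149). The exact permutation called each of these as well (0.0452). Camera there called glycolysis without Day 0 replicate 1 (0.0367) or 2 (0.0276), and hypoxia response without Day 0 replicate 1 (0.0342). With an estimated correlation camera called no list there. Of 14 retinoic acid genes 5 fell and 2 rose in controls against Day 0 (camera adjusted p = 0.0619, and 0.0373 without Day 0 replicate 4, but adjusted p = 0.298 with an estimated correlation). The adjusted p was 7.44e-04 with fry and 0.0538 with the exact permutation. Those that fell include Stra6, the binding protein gene Crabp2 (-1.34) and the retinoic acid degrading enzyme gene Cyp26b1 (-0.75), and under compression the values against Day 0 were -2.27, -1.38 and -0.91. Of 16 glycolysis genes 7 rose and 1 fell in controls (camera adjusted p = 0.128, and 0.0491 and 0.0366 without Day 0 replicates 1 and 2, but adjusted p = 0.875 with an estimated correlation), with Aldoc at 1.30 and Hk2, a hexokinase, at -0.78. Of 24 hypoxia response genes 9 rose and 5 fell (camera adjusted p = 0.485), with Pdk1 at 0.78 and Vldlr at 1.04, and of 31 respiratory chain genes 4 rose and 4 fell (0.641). Of 6 skeletal muscle genes 4 rose (camera adjusted p = 0.0972), with the myosin genes Myh8 at 3.01 and Mylpf at 1.21. The list was called without Day 0 replicate 1 (0.0488), Day 0 replicate 3 (0.0481), control replicate 1 (0.0367) or control replicate 2 (0.0401), but had an adjusted p = 0.625 with an estimated correlation, 0.00467 with fry and 0.0538 with the exact permutation.

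Some lists lay on opposite sides in time and under compression, and for 4 of them 0 of the 6 control splits gave the same sign for both. The mean score of heart muscle was 0.83 higher in controls than at Day 0 and -0.36 under compression relative to controls, and that of cholesterol synthesis 0.41 and -0.17. The cartilage list had -0.24 over time and 0.22 under compression, and BMP signalling -0.24 and 0.12. These lists were chosen after their values were seen. In this order their exact permutation p-values were 0.0857, 0.0286, 0.143 and 0.0286 over time (adjusted p at least 0.0538) and 0.343, 0.0286, 0.0857 and 0.171 under compression (adjusted p at least 0.525). For compression against control, camera did not call heart muscle with all libraries (adjusted p = 0.105, and 0.849 with an estimated correlation). It called heart muscle as lower without compression replicate 4 (0.00143) or control replicate 2 (0.00219). The opposition of the signs itself was not tested.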
